A study of Mus musculus with 4 samples.

How the data were processed

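Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers DNA bound by a protein with an antibody and counts the fragments along the genome. The samples were mouse fetal liver collected at embryonic day 14.5, when the liver is the main site of red blood cell formation. Per the labels, 4 livers lacking Klf3 on a Balb/c background were pooled, and a rabbit polyclonal antibody against KLF1 was used. KLF1, also called EKLF, is a zinc finger transcription factor of red cell precursors. Input DNA, which was not precipitated, served as the control. The 4 samples fell into 2 groups, KLF1 ChIP and input, and each group was sequenced once on SOLiD System 2.0 and once on System 3.0.

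Per the labels, the deposited files held the data of both sequencing systems combined. Each group was therefore a single combined library, the runs could not be separated, and no value has a replicate error. The deposited read files gave the chromosome, position and strand of each aligned read on the mouse build mm9, named in the submitters' processing notes. The aligner, the peak caller and their versions were not given in the sources used here. No reads in either file shared both position and strand, so removing duplicates would have changed nothing. On chromosome M alone, 6438 input reads lay within 0.0163 Mb without sharing position and strand, which points to duplicates collapsed before deposit. That step is not described in the sources used here. Heights therefore count each position and strand at most once.

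The fourth column of the deposited peak list was taken as a signal, the pileup height of the authors' combined ChIP reads. It equalled the number of ChIP reads covering the listed start, each extended to 101 positions from its 5' end, for 945 of 945 peaks. The listed intervals were 0 to 87 positions wide, with a median of 6, and so marked summits rather than bound regions. Coordinates are printed as deposited, and whether they count from 0 or 1 is not given in the sources used here. Heights were not scaled to library size or corrected for input.

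The tests were fixed before the data were examined. The planned count took reads with the 5' end inside the listed interval, with 1 read added to each count, and scaled each library to all its aligned reads. A ratio of 5 or more was counted as enriched. A one-sided exact binomial test compared ChIP reads among ChIP plus input reads with the libraries' share of all reads, with Benjamini-Hochberg adjustment over the peaks and a threshold of 0.05. Because the intervals marked summits, this planned count held few reads. A second count of 200 bp around the peak centre, also fixed beforehand, and an added count of reads covering the summit, chosen after seeing the data, are given beside it. The summit count uses the same reads that set the authors' height, and the 200 bp count holds most of them, so the enrichment in both is partly fixed by the choice of peaks. The planned count is not free of this, since the same ChIP reads placed the listed intervals. These tests compare 2 libraries, not conditions. Intervals for single ratios and shares are exact Clopper-Pearson 95% intervals and cover counting error only.

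Windows of 200 bp were scanned for 5-fold enrichment at an adjusted one-sided exact binomial p under 0.01, and windows within 200 bp of a listed summit were set aside. The same scan was run with ChIP and input exchanged. Peaks with a neighbour within 10 kb were counted and compared with 1000 random placements on the same chromosomes. The rule for named sites, the 20 highest peaks by the authors' height, was also fixed beforehand. Any other site named was chosen after its values were seen.

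Several measures were added after seeing the data. Regions of height 9 or more were called again from the reads, merged within 200 bp, and compared with the list. The same calling was applied to 20 random parts of the input, each of ChIP depth, with the remaining input reads as control. Reads 101 to 300 bp from the summit, which do not cover it, gave a flank ratio of ChIP to input. Its 95% interval came from 10000 resamples of peaks. Peaks per chromosome were compared with the share of input reads by two-sided exact binomial tests, adjusted over 20 chromosomes. The ChIP reads were also thinned to lower depth, in 10 draws per depth. A longer read extension of 151 positions was tried for the summit count and the region calling.

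The region calling was tested on simulated data, in which sites with known numbers of reads were added to an input background at ChIP depth. It recovered 8 of 50 sites with 6 added reads, 48 of 50 with 10, 49 of 50 with 15 and 50 of 50 with 25. All added reads covered the site once extended, so sites with 10 or more met the height limit of 9 by construction. Sites with more widely spread reads, and false calls, were not tested by this simulation. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

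The gene table at hand was of another genome build than the reads, and no mm9 sequence was used here. Sites are therefore given by mm9 coordinates, without genes. The planned comparisons of promoters, gene bodies, sequence motifs, 16 gene lists and coverage of Klf3 were not run.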

Results

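KLF1 occupancy in fetal liver was measured by ChIP-seq against input DNA. The combined ChIP library held 17438921 aligned reads and the combined input library 47356494. Each group was 1 combined library, so no difference below could be set against a replicate spread.

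The authors' list held 945 KLF1 peaks on the 19 autosomes and chromosome X. Most were low. The height, the authors' pileup of ChIP reads at the summit, ranged from 9 to 57 with a median of 11, and 441 peaks (46.7%) had a height of 9 or 10. At the other end, 105 peaks reached 20 or more. The highest lay on chromosome 17 at position 35878969, where 57 ChIP reads and 3 input reads covered the summit, a ratio of 51.6 after scaling to library size (95% interval 16.8 to 258). On chromosome 6 the summit at 72229669 had a height of 47 and a ratio of 21.3 (9.08 to 60.9). A summit of the same height on chromosome 8 at 19984277 had a ratio of 10.6 (5.56 to 22.0). The summit on chromosome 17 at 26651596 had a height of 44 and a ratio of 59.7 (15.6 to 509), and that on chromosome 14 at 70866215 a height of 42 and a ratio of 114 (19.4 to 4611), with 1 input read.

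The other sites among the 20 highest had heights of 31 to 37. They lay on chromosome 16 at 8655920, on chromosome 15 at 85935903, 80591622 and 56455310, on chromosome 11 at 32151066 and on chromosome 3 at 103708832. Chromosome 4 held 62177796, 151100744, 151334799 and 34497718, and chromosome 17 held 29067432 and 26079773. The rest were chromosome 1 at 36148310, chromosome 18 at 32702272 and chromosome 8 at 126512748. With 1 read added to each count, the 20 sites were enriched 8.89-fold to 58.4-fold over input at the summit. Counting reads that start more than 100 and up to 300 bp from the summit, and so do not cover it, they were enriched 2.08-fold to 22.2-fold.

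The comparison of ChIP with input at the listed peaks depended on the region counted. By the planned count of 5' ends inside the listed intervals, 572 of 945 peaks were enriched 5-fold or more, and 0 passed the one-sided exact binomial test after Benjamini-Hochberg adjustment. The lowest adjusted p of that exact test was 0.311, and 10 peaks had an unadjusted p under 0.05. The intervals held a median of 1 ChIP read, and 566 peaks had at least 1 ChIP read and no input read. A single ChIP read without input already gives 5.43-fold. Within 200 bp around the peak centre, 696 peaks were enriched 5-fold or more and 943 passed. Counting reads that cover the summit gave 928 and 945. Both of these counts hold the reads that set the height by which the peaks had been listed, so neither tests the peaks independently. Nor does the planned count, since the listed intervals lie where the same ChIP reads pile up. Reads that bound a summit can have their 5' end inside it by construction. The planned 5-fold count and share of reads are therefore also partly fixed by the choice of peaks.

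The listed intervals held 0.0061% of ChIP reads (0.0057% to 0.0065%). The 200 bp around the centres held 0.0866% (0.0853% to 0.0880%) of ChIP reads and 0.0113% (0.0110% to 0.0116%) of input reads, a ratio of 7.68.

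Enrichment was also seen beside the summits. Over all 945 peaks, ChIP exceeded input 2.29-fold in these flanks (95% interval 2.18 to 2.40). At 2 to 10 kb the ratio was 1.01. The flank ratio was 1.43 (1.32 to 1.54) for the 284 peaks of height 9, 1.95 (1.79 to 2.11) for the 157 peaks of height 10 and 4.32 (3.86 to 4.82) for the 105 peaks of 20 or more. Across peaks, which are not independent replicates, height and flank enrichment had a Spearman rho of 0.443 and, on the log2 scale, a Pearson r of 0.45. Both had a permutation p of 1e-05, the smallest that 100000 permutations can give.

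**Figure D1:**
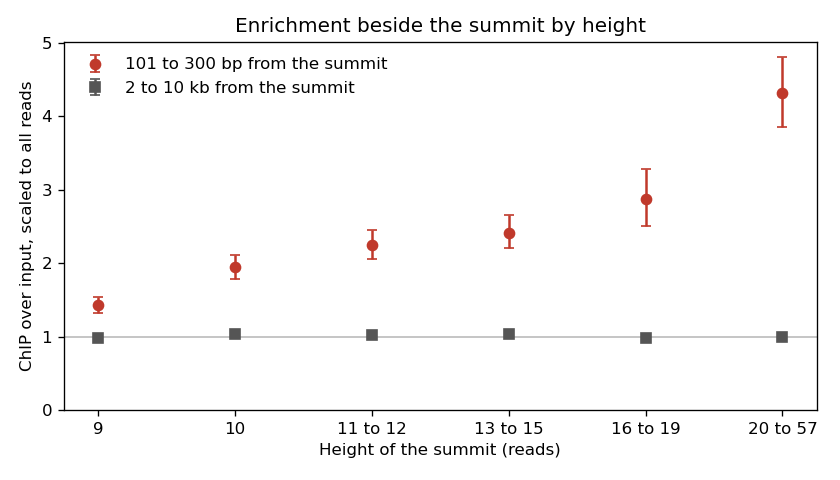
ChIP over input reads, scaled to all reads of each library, by height of the listed summit. Circles show reads in the flanks, more than 100 and up to 300 bp from the summit, with 95% intervals from resampling peaks, and squares show reads 2 to 10 kb away, with exact 95% intervals. The flank ratio was 1.43 at height 9 and 4.32 at 20 or more, while the distant ratio stayed between 0.982 and 1.03.

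Reads on opposite strands leaned to opposite sides of the summits. Upstream, 60.03% of ChIP reads in the flanks were on the forward strand (58.5% to 61.5%, two-sided exact binomial p = 2.29e-37), and downstream 40.0% were (38.5% to 41.5%, p = 3.05e-40). In the input the shares were 50.8% (49.4% to 52.2%) and 49.0% (47.6% to 50.4%), with exact binomial p = 0.28 and p = 0.172.

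**Figure D2:**
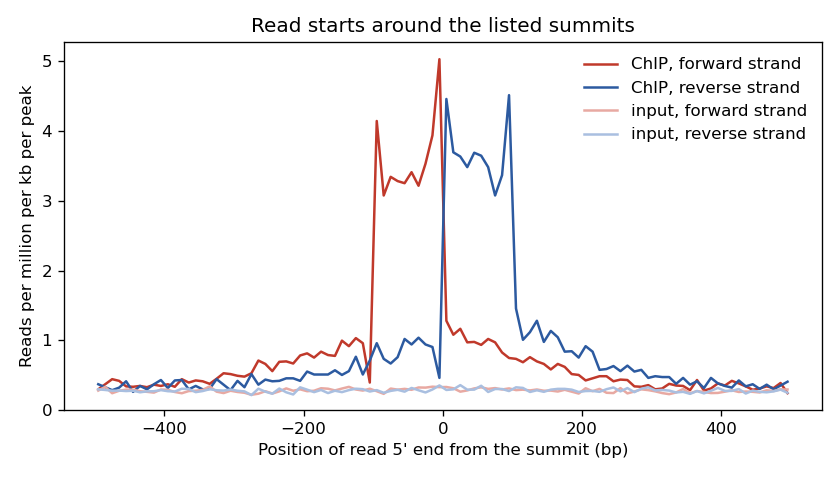
Mean density of read 5' ends around the 945 listed summits, per kb and peak and scaled to library size, by library and strand. The horizontal axis gives the distance from the summit in bp. Forward ChIP reads lie upstream of the summit and reverse reads downstream, and the sharp steps within 100 bp follow from defining a summit by the reads that cover it.

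The background of the list was measured in the input. Called from the reads by height of 9 or more and 5-fold enrichment over the summit, the ChIP library gave 965 regions, of which 928 held a listed peak. Random parts of the input of the same depth gave 346 ± 18.8 such regions (mean ± SD over 20 draws). This background depended on the read extension: at the longer extension that was tried, the ChIP gave 1847 regions and the input draws 1719 ± 25.7. At height 9 the draws gave 282 ± 16.1 regions, against 294 ChIP regions called the same way and 284 listed peaks. At height 10 they gave 46.5 ± 7.24 against 163 ChIP regions, and at 11 or more 17.7 ± 5.69 against 508. The authors' own calling rule was not given in the sources used here, and 17 listed peaks were under 5-fold at the summit. No draw gave a region of height 20 or more at 5-fold enrichment. The draws were compared with the remaining input, a shallower control than the ChIP library had, and their SD covers the random choice of reads only.

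**Figure D3:**
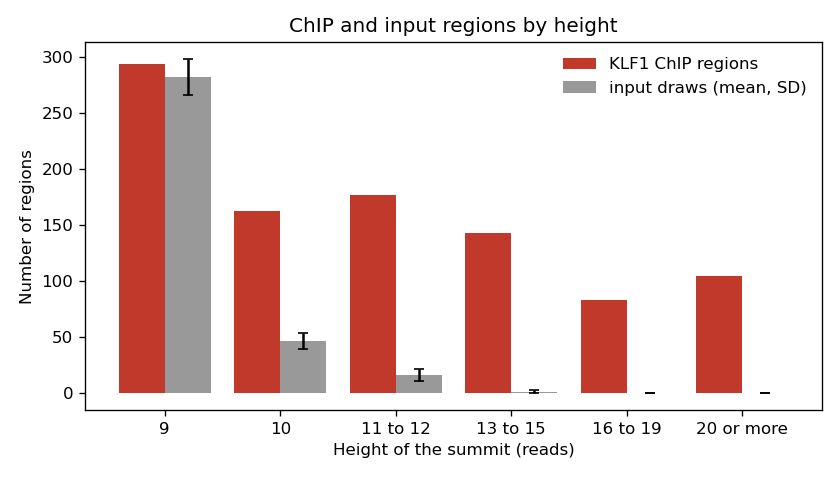
Number of regions of height 9 or more at 5-fold enrichment in the ChIP library and, called the same way, in random parts of the input, by height of the summit in reads. Input bars are means over 20 draws with SD. At height 9 the bars stand at 294 and 282, and ChIP regions outnumber input regions from height 10 upward.

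Outside the list, the calling from reads found 37 further regions of height 9 or more at 5-fold enrichment. Some lay beside a listed summit, such as 82836024 on chromosome 18 beside the listed 82836308, so not all are separate sites. The same calling on input draws gave 282 regions of height 9 and 46.5 of height 10. The scan of 200 bp windows found 205 past both limits, of which 200 lay at a listed peak and the others formed 5 sites. With ChIP and input exchanged, 5 sites outside the list passed as well. Since 200 windows passed at the 945 listed peaks, the scan would miss most sites of such heights.

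KLF1 peaks occurred in groups. Within 10 kb of another peak lay 112 peaks, against a mean of 7.61 for random placements (SD 4.02, highest 22), with a one-sided permutation p of 0.001, the smallest that 1000 placements can give. They formed 51 groups, of which 44 were pairs and 7 held 3 or 4 peaks. Some pairs were close, such as that on chromosome 4 from 118862630 to 118863391, with heights of 30 and 9. Not all grouped peaks need therefore be separate sites. A group of 4 on chromosome 6 from 38853236 to 38874284 had heights of 15, 22, 22 and 10. On chromosome 5 from 118930175 to 118942727 the heights were 12, 9, 13 and 11, and on chromosome 11 from 115368085 to 115374725 they were 10, 11, 10 and 9. Another group on chromosome 11, from 32145726 to 32156244, held 1 of the 20 highest peaks, with heights of 10, 35 and 9. On chromosome 7 from 111007774 to 111019397 the heights were 17, 13 and 10. Among input regions at 5-fold enrichment, the highest in any of the 20 draws had a height of 17.

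Peaks were not spread evenly over chromosomes. Chromosome 11 held 81 peaks against 53.4 expected from its input reads (1.52 times, 95% interval 1.22 to 1.87, adjusted two-sided exact binomial p = 0.0024). Chromosome 19 held 38 against 24.1 (1.58 times, 1.12 to 2.15, adjusted exact binomial p = 0.0463). Chromosome X held 7 against 31.9 (0.22 times, 0.0885 to 0.451, adjusted exact binomial p = 3.63e-06). From covered length instead of input reads, 59.96 were expected and the ratio was 0.117. Autosomes thinned to the density of chromosome X predicted 13.5 called regions over its covered length against 9 seen (two-sided exact Poisson p = 0.273). These were called regions, not listed peaks, and too few to show whether a deficit remains at matched read density. The other 17 chromosomes did not pass. Among peaks of height 11 or more, chromosome 11 was at 1.33 times and chromosome 19 at 1.56 times the expected number. Each had an adjusted exact binomial p of 0.212. Chromosome 4 was at 1.51 times there (1.12 to 1.99, adjusted exact binomial p = 0.0632), and at 1.23 times among all peaks. With grouped peaks counted once, chromosomes 11 and 19 were at 1.40 times (adjusted exact binomial p = 0.0547) and 1.55 times (p = 0.0895, same exact test). The calls on chromosomes 11 and 19 were lost in both settings, which held fewer peaks. At height 11 or more their intervals included 1 (0.954 to 1.81 and 0.957 to 2.38). The ratio on chromosome 11 also fell, and why the calls were lost was not tested.

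**Figure D4:**
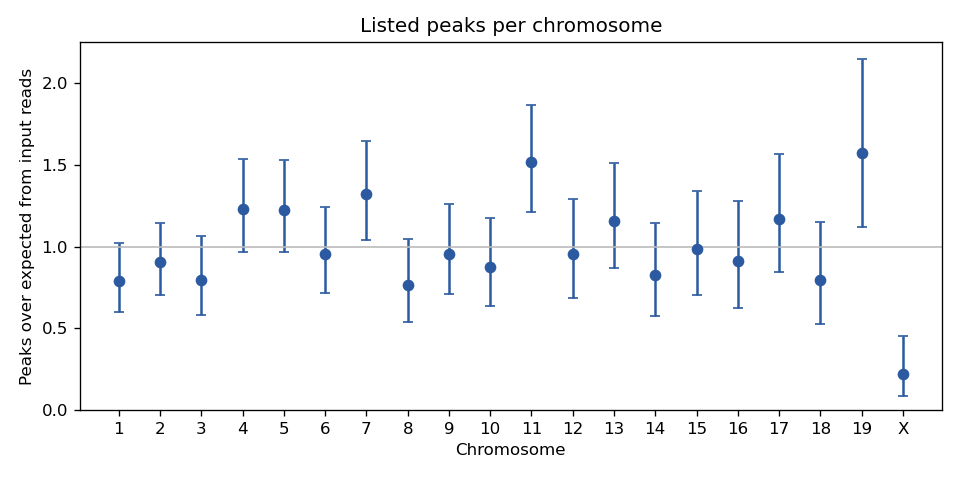
Listed peaks per chromosome divided by the number expected from the chromosome's share of input reads, with exact 95% intervals. The line marks a ratio of 1. Chromosomes 11 and 19 lie above it at 1.52 and 1.58, and chromosome X below it at 0.22.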

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

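The tests in this part were chosen after the results were seen. No peak was listed outside the autosomes and chromosome X, but ChIP reads exceeded input reads, scaled to all reads, on several other sequences. The ratio was 1.76 on chromosome Y (95% interval 1.69 to 1.83), 1.96 on the unplaced Y sequence (1.92 to 2.01) and 1.87 on unplaced sequence of no chromosome (1.85 to 1.89). It was also raised on unplaced sequence of chromosome 4 at 1.497 (1.36 to 1.65), of chromosome 8 at 1.32 (1.24 to 1.40) and of chromosome 9 at 1.16 (1.11 to 1.21). The unplaced sequence of chromosome 1 was at 0.989 (0.95 to 1.03), of chromosome 13 at 0.947 (0.838 to 1.07) and of chromosome X at 0.883 (0.837 to 0.93). Autosomes ranged from 0.97 to 1.05. Per the labels the sex was female, yet both libraries held reads on chromosome Y, 4443 in the ChIP and 6856 in the input. Whether the label describes the livers or the mothers is not given in the sources used here. Regions of height 9 or more at 5-fold enrichment that were not in the list numbered 37, with heights of up to 14.

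The excess on chromosome Y was weighed further. It did not come from the densest 10 kb bins alone, since 189 bins of 10 kb with 10 to 60 input reads had a ratio of 1.72 (1.65 to 1.79). These bins held most of the reads on chromosome Y, and they cannot show reads piled up over shorter stretches within them. Whether collapsing of duplicates before deposit affected the ratio was not tested. Repeated sequence of ordinary read density was not tested and stays open. A larger share of male DNA in the ChIP than in the input would raise chromosome Y and lower chromosome X, whose ratio of 0.93 (0.927 to 0.933) lay below every autosome, but the X and Y ratios together would need 16.8% male DNA in the input and 29.5% in the ChIP, and so an X density of 91.6% and 85.2% of the autosomes, where 51.5% and 47.9% were seen. This explanation stays open only because the share of chromosome X that reads can be aligned to was not measured, and it cannot account for the raised unplaced sequence of chromosomes 4, 8 and 9; no biological explanation was tested.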

How the results depend on the processing

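Of 40 alternatives over 11 results, 24 were chosen after seeing the data; 17 kept the result, 19 moved it and 4 ended a call. The number of peaks enriched 5-fold or more, 572 as planned, was 8 at 10-fold and 928 for reads covering the summit. It was 404 with reads moved 50 bp, 696 within 200 bp and 781 for reads covering the summit at the longer extension. These last alternatives were among those counted as keeping the result, so that label does not mean the number stayed close to 572. The number past the binomial test, 0 as planned, was 44 with reads moved 50 bp, 943 within 200 bp, and 945 for reads covering the summit, also at the longer extension (945). The planned intervals held a median of 1 ChIP read and at most 4. The 200 bp and summit counts held most or all of the reads that set the height. The share of ChIP reads in peaks, 0.0061%, was 0.0069% with reads moved, 0.0866% within 200 bp, 0.0026% for peaks above the median height and 0.0705% for reads covering the summit. Enriched sites outside the list numbered 9 with 500 bp windows and 2 at 10-fold, where the exchanged scans gave 2 and 5. Peaks with a neighbour numbered 224 within 50 kb (random mean 37.4) and 27 above the median height (random mean 1.26), each still past the permutation test. Called regions numbered 510 when stretches of height 11 or more were called and merged anew (508 of the 965 main regions reached that height) and 1847 at the longer extension, where input draws gave 1719. The flank ratio of all peaks was 2.63 in flanks up to 200 bp and 1.81 in flanks up to 500 bp, and that of height 9 peaks 1.29 in flanks up to 500 bp. For peaks of height 11 or more, the excess was 1.33 on chromosome 11 and 1.56 on chromosome 19, and with groups counted once 1.40 and 1.55, none past the threshold. Fewer peaks were tested, and the cause was not tested further. The ratio on chromosome X was 0.117 from covered length, past the threshold as before. Removing duplicates would have moved nothing. Leaving out a sequencing run, and all alternatives that need genes or sequence, were not run.

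With 25%, 50% and 75% of the ChIP reads, 60.5 ± 6.20, 228 ± 9.36 and 537 ± 11.3 regions were called (mean ± SD over 10 draws), against 965 with all reads. Thinning lowers every height while the limit of 9 stays fixed, so these counts do not show whether sites were missed.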

Other observations

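The tests in this part were chosen after the results were seen. The number of listed peaks of height 9 was close to that of input regions of the same height, though the authors' calling rule is not known, and sampling noise in the reads may account for part of them: input draws gave a mean of 282.1 regions against 284 listed peaks. Noise alone would give flanks like those of the input regions, whose ratio had a mean of 0.952 and a highest value of 0.998, but the flank ratio of the listed peaks was 1.43 (1.32 to 1.54). A local excess of ChIP reads reaching 2 to 10 kb from the summit was argued against by the ratio of 0.982 there. Ratios between 500 bp and 2 kb were not measured, so an excess ending short of 2 kb stays open. How many peaks of height 9 are bound by KLF1 stays open, and no biological explanation was tested.

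The low number of peaks on chromosome X may reflect its read density, which was 47.9% of that of the autosomes in the ChIP and 51.5% in the input. Regions called from the reads numbered 9 on chromosome X, against 64.6 expected from autosomes at full depth by covered length, a baseline other than the input reads used for the listed peaks. Autosomes thinned to the density of chromosome X predicted 13.5 over the same length (two-sided exact Poisson p = 0.273). With so few regions, a difference beyond read density was not detectable at this depth and stays open.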
